A study of Homo sapiens with 5 samples.

How the data were processed

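Genomic DNA (gDNA) barcode libraries were analysed from 5 samples of MEC1, an established human B-cell line derived from chronic lymphocytic leukaemia. Per the labels and the series' design text, the cells carried Cre recombinase and a landing pad for recombinase-mediated cassette exchange inside the AXIN2 gene, and received by electroporation a plasmid library in which each inserted regulatory sequence is joined to barcodes. Per the labels, gDNA was extracted with a kit for DNA and RNA, and the series' design text states that barcodes were sequenced from mRNA and gDNA. The labels number the libraries from 1 to 5 and do not say whether they came from separate transfections, cultures or extractions, so the spread between them may be technical. AXIN2, a negative regulator of Wnt signalling, is a protein-coding gene on chromosome 17 in the reference gene table used here. The position of the landing pad within the gene is not given in the sources used here.

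The authors deposited one list of reads per library, in which each read has its barcode bases, and a summary table of raw read counts per barcode and library, in which barcodes are grouped by the name of the inserted sequence. The summary table pairs each barcode of 12 bases with 1 inserted sequence. Its gDNA values are counts with no normalization, as the check against the read lists described below showed. The trimming tool, the sequencing data that tied barcodes to inserted sequences, the filters and the genome build of named intervals are not given in the sources used here. Neither the read lists nor the table carries molecular identifiers, so reads are not independent molecules, and exact intervals and floors cover counting error only. The table also held 5 columns of per-sample values that match no sample of this series; these were not used in any step, so no measure of expression from the inserted sequences is reported. The inserted sequences themselves were not analysed here, only their names.

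The table was checked against the read lists. The reverse complement of the barcode bases in each list gave exactly the deposited count for 148649 of 148649 barcodes in each of the 5 libraries. A single read in library 2 had a string of another length than 12 bases and was not in the table's total. Reads whose barcode the table gives under no inserted sequence stand in 1 row of the table; this row took 29.1% ± 0.221 (SD, n = 5) of reads and was left out of library sizes and tests. Listing in the table depended on read number. Among strings whose highest count over the 5 libraries was 9 reads, 37.4% were listed (95% exact interval 35.6 to 39.2), and at a highest count of 10 reads 73.7% were listed (72.1 to 75.3).

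Inserted sequences were grouped by their names as deposited. Names holding GENERATED and a cell line (GM12878, HepG2 or K562) formed 3 classes of 60, 10 and 10 sequences, names giving a chromosome interval formed a class of 15, and names marked as shuffled from a generated GM12878 sequence formed a class of 5. The other 6 names (ref, alt, wt_enh_del, wt_MF2A_PU1_MF2A, wt_MF2A_SPI1_FX1_BH1 and wt_MF2A_SPI1_FX1_TF65) were kept apart, and their abbreviations were not interpreted. A barcode counted as detected in a library with at least 10 reads there. Reads of detected barcodes were summed per inserted sequence and scaled to 1000000 reads of detected barcodes per library (CPM), and shares are percentages of the same total. Reads per barcode are means over detected barcodes.

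Classes were compared on the mean over libraries of log2(CPM + 1) per inserted sequence, with a two-sided permutation test of the difference in class means over sequences. All splits were enumerated where there were at most 10000000 of them (exact test), and 100000 resamples were drawn otherwise. Benjamini-Hochberg adjustment covered the 10 class pairs, with a threshold of 0.05. Intervals of class differences are 95% bootstrap intervals over sequences (10000 draws) and cover the spread between sequences. The unit of these tests is the inserted sequence, not the library. Agreement between libraries was described by Pearson and Spearman correlation across barcodes with a mean of at least 10 reads, whose counts were scaled to all assigned reads of a library; barcodes are not independent replicates and no p-value was computed. No groups of samples were compared, because all 5 libraries form 1 group; Dixon's criterion was used to find single libraries that stood apart from the others. Named sequences were all sequences outside the 5 classes and, in each class, the 5 highest and the 5 lowest. This rule was adapted from one set before the data were examined. The earlier rule named control or endogenous sequences in place of those outside the classes. It was written for expression per gDNA copy and was applied to gDNA CPM instead. Its criterion that most barcodes of a sequence lie on the same side of a reference class could not be applied. The adapted rule gave 51 sequences. A further 4 in the text fall outside it and were named after their values were seen, as members of compared pairs: 31433_GENERATED_GM12878, 75119_GENERATED_GM12878, 82101_GENERATED_GM12878 and the chromosome 10 interval starting at 7472030.

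The class test was tested on simulated data with 60 against 10 sequences of equal SD. Of 100 draws without a difference, 4 had p under 0.05, and 100 of 100 draws with a shift of 2 log2 units did. Classes of unequal SD, as in these data, and 60 against 15 sequences were not simulated. The exact test above, the neighbour search and the calculation of variance over mean were also tested on simulated data, the last with 148649 barcodes. Alternatives were a read minimum of 1 or 100, every barcode string, another pseudocount, barcodes in place of reads as the unit, leaving out each library in turn and, chosen after seeing the data, barcodes with 6 to 8 G or C bases only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.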

Results

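The 5 gDNA libraries measured how often each of 106 named regulatory sequences was recovered by its barcodes. The sequences had been delivered to MEC1 cells with a landing pad in AXIN2. Integrated copies were not told apart from unintegrated plasmid. The set held 80 sequences generated for 1 of 3 cell lines, namely GM12878, a B-lymphoblastoid line, HepG2, a hepatocellular carcinoma line, and K562, an erythroleukaemia line. It further held 15 sequences named by genomic interval, 5 shuffled sequences and 6 others. Libraries 1 to 5 held 5386817, 6041756, 6024017, 6143315 and 5160616 reads, of which 3827964, 4287819, 4273195, 4373042 and 3642970 carried a listed barcode.

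All 106 sequences were recovered in every gDNA library, but at very unequal levels. The sequence named wt_enh_del was the most abundant, with 58374 ± 694 CPM (SD, n = 5), or 5.84% of reads of detected barcodes. The least abundant was the interval on chromosome 22 named 22935643 to 22935843, with 365 ± 68.1 CPM, so the range spanned 160-fold. The median sequence had 7627 CPM, against 9434 CPM for an equal share, and the 24 most abundant sequences together held over 50% of reads. Between libraries the coefficient of variation of a sequence's level had a median of 2.62% and ranged from 0.619% to 18.7%, the highest being that of the chromosome 22 interval. The range over sequences was far larger than this spread.

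**Figure D1:**
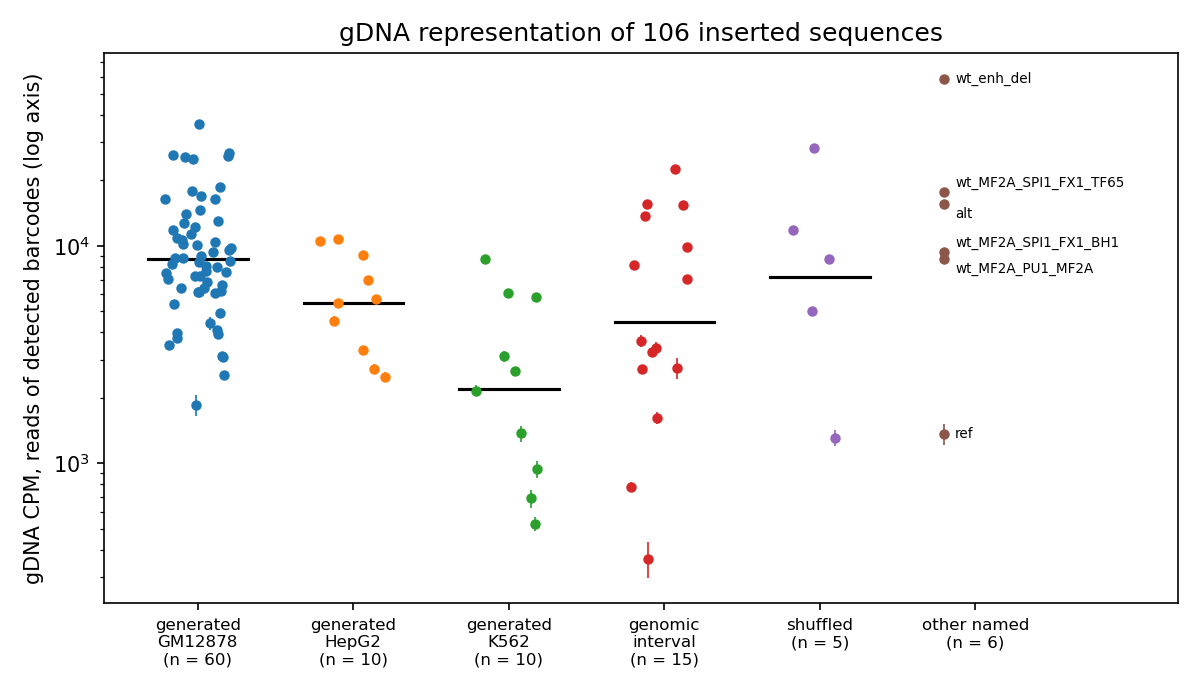
Mean gDNA level (CPM of reads of detected barcodes, log axis) of each of the 106 inserted sequences, by class; points are means over 5 libraries, bars are SD, and black lines are class means of log2 values. The generated K562 sequences lie lowest as a class, from 527 to 8716 CPM, and wt_enh_del lies above all others at 58374 CPM.

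Sequences generated for GM12878 held most reads of detected barcodes, and they were also 56.6% of the 106 sequences. The 60 of them took 63.0% ± 0.153 (SD, n = 5) of these reads, with a median of 8462 CPM. The highest was 99984_GENERATED_GM12878 at 36281 ± 733 CPM, followed by 54804_GENERATED_GM12878 at 26674 ± 549 CPM and 82375_GENERATED_GM12878 at 26195 ± 305 CPM. The lowest were 72365_GENERATED_GM12878 at 1860 ± 213 CPM and 38266_GENERATED_GM12878 at 2555 ± 114 CPM. The 10 HepG2 sequences took 6.16% ± 0.0244 of reads and ranged from 2500 ± 139 CPM for 96333_GENERATED_HEPG2 to 10750 ± 269 CPM for 14156_GENERATED_HEPG2. The 10 K562 sequences took 3.21% ± 0.0567 and ranged from 527 ± 40.0 CPM for 92295_GENERATED_K562 and 690 ± 63.4 CPM for 65517_GENERATED_K562 to 8716 ± 275 CPM for 70305_GENERATED_K562.

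The generated K562 sequences were rarer in gDNA than the generated GM12878 sequences. Their mean log2(CPM + 1) was 11.10 ± 1.39 (SD over 10 sequences) against 13.08 ± 0.90 (SD over 60 sequences), a difference of 1.98 (95% bootstrap interval 1.13 to 2.83), or 3.95-fold. The permutation test gave an adjusted p of 0.0001, which rests on the smallest p that 100000 resamples can give, 1e-05. The sequences named by genomic interval, at 12.13 ± 1.69 over 15 sequences, were also below the GM12878 sequences, by 0.95 (0.13 to 1.83, permutation test, adjusted p = 0.0186). In both comparisons the smaller class had the wider spread, 1.39 and 1.69 against 0.90. A permutation test of means can then give p-values that are too small. The difference for genomic intervals is therefore tentative. The HepG2 sequences, at 12.41 ± 0.77, were not separated from the GM12878 sequences after adjustment (difference 0.67, interval 0.17 to 1.18, permutation test, raw p = 0.0304, adjusted p = 0.076), nor from the K562 sequences (1.31, interval 0.38 to 2.25, exact permutation test, adjusted p = 0.0623). The other 6 of the 10 class pairs did not pass the threshold.

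The GM12878 and K562 classes differed in the number of detected barcodes and were not separated in reads per detected barcode. Detection needed at least 10 reads, so barcodes with fewer reads lower the first measure and drop out of the second. A difference in reads per barcode is therefore not excluded. Listing also favoured strings with at least 10 reads. The GM12878 sequences had a median of 1216.5 listed barcodes each, the HepG2 sequences 894.5, and the K562 sequences 349. In detected barcodes per library, the GM12878 and K562 classes differed by 1.98 on the log2 scale (permutation test, adjusted p = 0.0001). Reads per detected barcode were 54.3 ± 2.53 (SD over 60 sequences) for GM12878, 52.8 ± 2.63 for HepG2, 54.5 ± 4.14 for K562, 54.3 ± 3.57 for genomic intervals and 55.8 ± 3.90 for shuffled sequences, and none of the 10 pairs differed on the log2 scale (adjusted p from 0.545 to 0.983, permutation tests). Over single sequences, reads per detected barcode ranged only from 47.9 to 63.5. Barcodes of the K562 sequences contained slightly more G and C than those of the GM12878 sequences, 52.0% against 51.4% (permutation test, adjusted p = 0.0121).

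The shuffled sequences, each named as shuffled from 1 of the GM12878 sequences, took 5.49% ± 0.0566 of reads. As a class they were not separated from the GM12878 sequences in level (difference 0.27, interval -0.94 to 1.63, exact permutation test, adjusted p = 0.600). Within the 5 matched pairs, the shuffled sequence was the more abundant for 31433 (8700 ± 169 against 4892 ± 144 CPM) and 75119 (11802 ± 333 against 6066 ± 189 CPM). The generated sequence was the more abundant for 99984 (36281 ± 733 against 28132 ± 328 CPM), 82101 (6133 ± 146 against 5006 ± 82.2 CPM) and 72365 (1860 ± 213 against 1307 ± 110 CPM). Each of these 5 differences had the same direction in 5 of 5 libraries. Over the pairs, the mean log2 ratio of shuffled over generated was 0.13 ± 0.71 (SD, n = 5 pairs; two-sided exact sign-flip permutation test, p = 0.688, with a smallest possible p of 0.0625).

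The genomic intervals took 11.1% ± 0.102 of reads. The genome build of their names is not given in the sources used here, and no gene annotation was attached to them. The most abundant was the interval on chromosome 5 named 3996041 to 3996241, at 22554 ± 388 CPM, followed by chromosome 13, 79194424 to 79194624, at 15521 ± 528 CPM, and chromosome 11, 12174637 to 12174837, at 15333 ± 462 CPM. The rarest, besides the one on chromosome 22, was chromosome 11, 67955537 to 67955737, at 781 ± 37.4 CPM. A pair of intervals on chromosome 10 with starts named 7472030 and 7472052 overlap in most of their length. They had 3253 ± 81.6 and 2738 ± 301 CPM, the first being higher in 5 of 5 libraries.

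The sequences named ref and alt differed strongly in representation. The ref sequence had 1368 ± 148 CPM on 172 listed barcodes, and alt had 15516 ± 113 CPM on 1854, which is 11.4-fold more. The log2 ratio of ref over alt was -3.51 ± 0.170 (SD, n = 5), and alt was higher in 5 of 5 libraries (two-sided exact sign-flip permutation test, p = 0.0625, the smallest that 5 libraries allow). The sequence named wt_enh_del exceeded alt 3.76-fold and ref 42.9-fold. The other 3 wt sequences lay between, with 17614 ± 453 CPM for wt_MF2A_SPI1_FX1_TF65, 9369 ± 104 CPM for wt_MF2A_SPI1_FX1_BH1 and 8661 ± 356 CPM for wt_MF2A_PU1_MF2A.

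The number of barcodes available to measure a sequence followed its representation. Representation is a sum of reads over those same barcodes, so this relation is partly built in. The table listed 148649 barcodes, between 83 and 8636 per sequence with a median of 1099. A library detected 74056 ± 2056 of them (SD, n = 5) with at least 10 reads, and these held 98.3% ± 0.488 of its assigned reads. Only 24966 barcodes (16.8%) reached 10 reads in all 5 libraries, and 43937 (29.6%) did so in exactly 1. A further 2782 listed barcodes had 0 reads in all 5 libraries. The floor of 3 reads, 0.694 to 0.843 CPM per library, covers counting error only, so higher levels are not excluded. Per sequence, between 9 and 1447 barcodes reached 10 reads in all 5 libraries. For 10 sequences fewer than 50 did; among them were ref with 39, shuffled_from_72365_GENERATED_GM12878 with 42, its parent with 43, 92295_GENERATED_K562 with 15 and 65517_GENERATED_K562 with 14.

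Single barcodes varied strongly between libraries. Across the 86269 barcodes with a mean of at least 10 reads, Pearson's r of log2(CPM + 1) ranged from 0.294 to 0.390 over the 10 library pairs and Spearman's rho from 0.309 to 0.397. The variance of a barcode's reads between libraries, after scaling to equal depth, was 24.0 times the mean for barcodes averaging 10 to 20 reads and rose to 37.9 times for the 152 barcodes averaging 500 reads or more; counting noise alone would give 1. The spread thus exceeded read-counting noise; sampling of template molecules was not measured. Summed per inserted sequence, the variance over mean had a median of 24.6 (quartiles 13.4 and 39.0), similar to that of single barcodes.

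**Figure D2:**
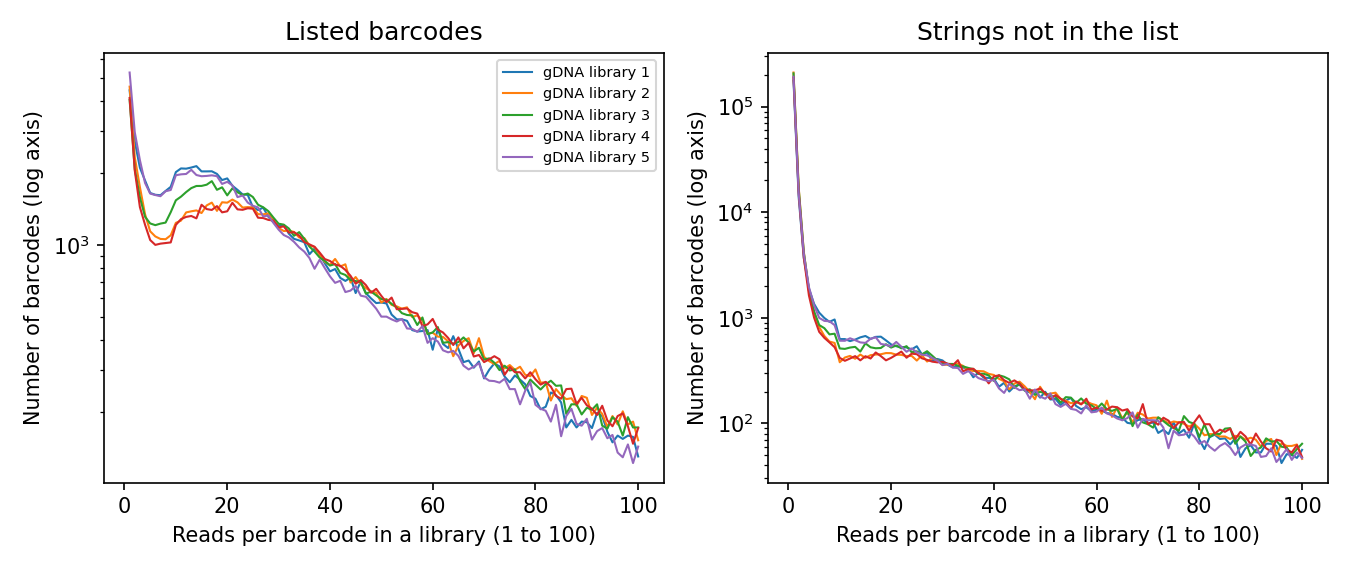
Number of barcodes (vertical log axis) by their reads in a library (horizontal axis, 1 to 100 reads), one line per gDNA library, for listed barcodes (left) and for strings not in the list (right). The commonest count of listed barcodes is 1 read, with a lower local peak between 13 and 21 reads depending on the library, and at 10 reads the number of listed barcodes steps up and that of unlisted strings steps down.

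Reads per barcode also followed the base composition of the barcode. Listed barcodes with 3 G or C bases of 12 averaged 14.5 reads per library and those with 8 averaged 32.1, a ratio of 2.21 ± 0.101 (SD, n = 5 libraries). Mean reads were 32.8 at 9 G or C bases, 30.0 at 10, 27.8 at 11 and 41.5 at 12, the last on only 93 barcodes. Median reads where at least 1 read was found went from 33 at 8 to 24 at 11 and 18 at 12. At least 10 reads were reached in 43.4% of cases (barcodes times libraries) with 3 G or C bases and in 50.6% with 8, while at least 1 read was found in 63.8% and 60.8%. Where at least 1 read was found, mean reads were 22.8 and 52.8. Because listing favoured strings with at least 10 reads, these values describe listed barcodes only. Mean barcode GC per inserted sequence stayed between 48.2% and 53.1%.

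**Figure D3:**
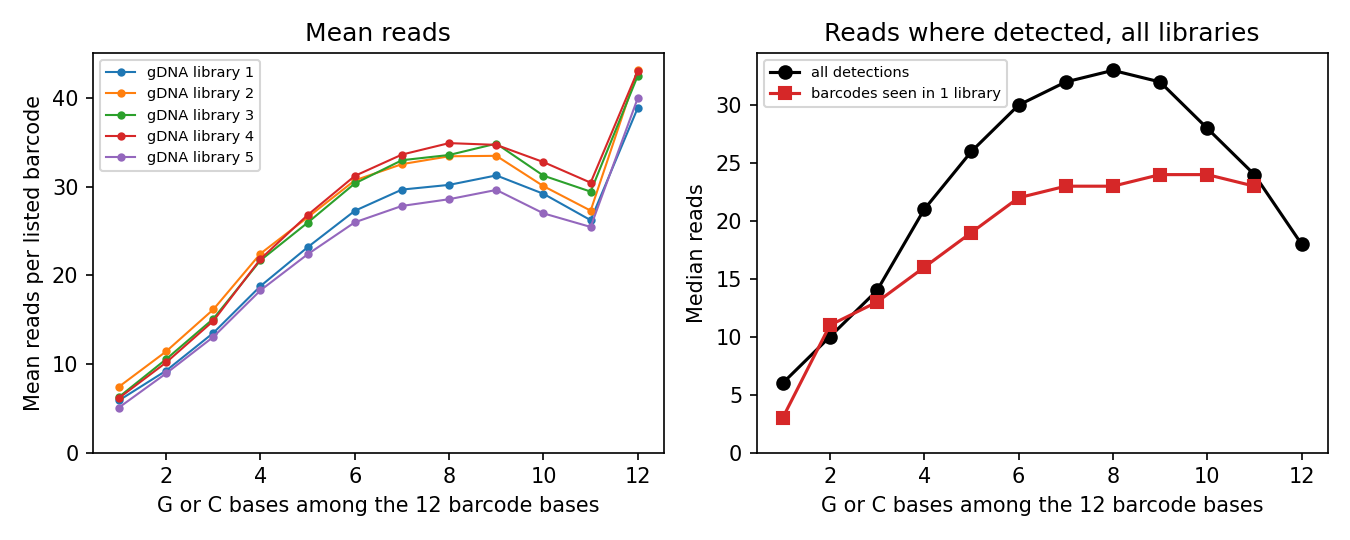
Mean reads per listed barcode in each gDNA library (left) and median reads where a barcode had at least 1 read (right). Both are shown by the number of G or C bases among the 12 barcode bases. On the right, black is all cases with at least 1 read and red is barcodes with at least 1 read in only 1 library. In every library mean reads rise from barcodes with 3 G or C bases to those with 8, by 2.21-fold on average. Averaged over libraries, mean reads are lower at 10 and 11 than at 9 and highest at 12, at 41.5, which rests on 93 barcodes.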

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

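The tests of reading errors, of a loss confined to abundant barcodes, of collisions among listed barcodes and of the needed collision rate were chosen after the results they bear on had been seen; the criteria for abundance and for base composition were set before. A library stood apart from the other 4 in 8 of 67 values examined with Dixon's criterion, which flags about 1 value in 20 by chance (3.35 expected here). Library 4 had the lowest share of generated HepG2 sequences, 6.11% against 6.16% to 6.17%. In library 4, 64077_GENERATED_HEPG2 also had 4121 CPM against 4562 to 4698 CPM, and 68879_GENERATED_K562 had 2423 CPM against 2688 to 2726 CPM. Since 64077_GENERATED_HEPG2 is part of the HepG2 class, its flag and that of the class share are not independent. Library 2 had the lowest share of wt_MF2A_PU1_MF2A, 0.804% against 0.872% to 0.892%, and the lowest level of 570_GENERATED_GM12878, 2916 CPM against 3144 to 3209 CPM. Library 1 had the highest share of wt_enh_del, 5.96% against 5.80% to 5.81%. Library 5 had the lowest share of ref, 0.111% against 0.139% to 0.150%, and the highest level of the chromosome 13 interval 79194424 to 79194624, 16423 CPM against 15051 to 15447 CPM.

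A signal appeared in reads that the comparisons above do not use. Per library, 23860 barcode strings outside the list had at least 10 reads (23275 to 24657 over the libraries), and they held 83.5% ± 1.27 (SD, n = 5) of the unassigned reads. They made up 24.4% ± 0.0952 of all strings at that level, and 8443 of them reached 10 reads in all 5 libraries. Their median reads were 32 to 40, against 31 to 38 for listed barcodes. Unlisted strings below 10 reads in every library differed from these: in a sample of 50000, 62.6% lay 1 base from a listed barcode, against 36.5% after their bases were shuffled.

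Single-base reading errors of listed barcodes do not account for the strings with at least 10 reads, whereas those below 10 reads may include many: of the 44556 with at least 10 reads in some library, 40.0% lay 1 base from a listed barcode (95% exact interval 39.5 to 40.4), against 38.3% after their bases were shuffled. A loss confined to abundant barcodes is argued against, because 23.9% of strings averaging 10 to 20 reads were unlisted (23.4 to 24.3). The unlisted share did rise with abundance, to 28.0% at 200 to 500 reads (26.1 to 29.9) and 38.0% of the 245 strings at 500 reads and above (31.9 to 44.4), but this rise of 1.59 times (1.31 to 1.89) stays below the 2 times set beforehand for such a cause, and its 14.1 percentage points (7.59 to 20.9) are not clearly within the 15 set against it. Chance sharing of a barcode by several sequences also stays open, since the unlisted share was 1.92 times as high in the decile of strings with the commonest base composition as in the rarest (1.81 to 2.04), between the limits of 1.3 and 2 set beforehand, and its interval includes the upper one. Tried afterwards, collisions among listed barcodes alone would number 1976, and the collision rate needed for these shares grew 2.17-fold (2.02 to 2.33) where base composition predicts 15.6-fold, but both rest on an assumed pool and exclude nothing.

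The design gives no biological explanation for the unlisted strings, and none was tested.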

How the results depend on the processing

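The alternative over barcodes with 6 to 8 G or C bases was chosen after seeing the data. All 10 class differences in log2(CPM + 1) kept their direction and their side of the threshold without a read minimum, with barcodes in place of reads, over barcodes with 6 to 8 G or C bases and without each library in turn. Leaving out 1 library moved the K562 difference between 1.98 and 1.99, and the count of detected barcodes between 73414 and 74484. Levels of sequences correlated at 0.997 to 0.998 between libraries (Pearson's r), so leaving out 1 library could hardly move a class difference. It does not test the spread between sequences, which the bootstrap intervals cover. The mean correlation across barcodes, 0.343 in the main setting, was 0.464 without a minimum, 0.251 with a pseudocount of 0.1 CPM, and 0.331 to 0.357 without 1 library. A minimum of 100 reads left 9207 detected barcodes per library; a minimum of 1 gave 91011, and counting every string 97916. As shares of detected barcodes, GM12878 sequences took 63.2%, HepG2 6.37%, genomic intervals 10.9%, shuffled 5.33%, alt 1.40% and wt_MF2A_SPI1_FX1_BH1 0.959%. Over barcodes with 6 to 8 G or C bases, HepG2 sequences took 6.27%, K562 3.30%, alt 1.496% and wt_MF2A_SPI1_FX1_BH1 0.995%. The cause of these shifts was not tested. Of the 55 named sequences, 32 moved by more than their SD between libraries when barcodes replaced reads, and 21 over the restricted barcodes. Counting molecular identifiers was not possible without them. The planned comparisons of expression by class and of motifs were not run, because they need mRNA counts of samples in this series and the inserted sequences, which were not analysed here. No paired analysis was possible because all libraries form 1 group and no samples of different groups could be paired; the sign-flip tests pair sequences. Barcodes averaging 10 to 20 reads had a variance of 24.0 times the mean, far above read-counting noise, so read depth is not shown to set their precision. For the same reason the floor of 0.694 to 0.843 CPM for a barcode with 0 reads covers counting error only and does not exclude higher levels.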

Other observations

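The tests of reads per barcode, of the reads per barcode of the K562 class and of its barcode numbers were chosen after the values they rest on had been seen, as was the restriction to barcodes with 6 to 8 G or C bases; only the criterion for that restricted comparison was set before its result.

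The commonest count of a listed barcode with any read was 1 in each of the 5 libraries, held by 4058 to 5279 barcodes. Among counts of 1 to 10 reads, the rarest was 6, 7 or 8 reads (1001 to 1616 barcodes), followed by a lower local peak at 14, 21, 17, 21 and 13 reads in libraries 1 to 5, searched between 8 and 60 reads (1503 to 2140 barcodes). The range searched was set after the result was seen, and the list's step at 10 reads adds to this local peak; over all strings from 5 reads the commonest count was 5. The 27699 listed barcodes with at least 1 read in only 1 library had medians of 18 to 24 reads, values that the step also raises.

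The variance of single barcodes between libraries was far above read-counting noise. A candidate explanation is that each barcode was read from a few template molecules, each copied into a family of about 20 reads. Variance above counting noise then grows in proportion to the mean (slope 1 on log scales), while a random amplification factor per barcode and library gives a slope of 2; simulated counts gave 1.01 and 2.11. The measured slope was 1.11 (95% bootstrap interval 1.07 to 1.16), 1.07 without the highest bin and 1.08 to 1.12 without 1 library. This slope lies far from the random factor as the main source. It lies close to families, though its interval excludes exactly 1. Only these 2 models were compared, so the slope cannot tell families of reads from other sources with a slope near 1. Variance over mean was 13.2 for barcodes with 3 G or C bases and 31.3 for those with 8, so a single family size is not shown. Dividing assigned reads by the median for barcodes seen in 1 library would give 182210 to 212665 templates per library, an estimate that depends on this hypothesis.

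The lower representation of generated K562 than of generated GM12878 sequences, 1.98 on the log2 scale, was examined for its source. Reads per detected barcode do not account for it, as the classes differed by -0.0041 on that measure (bootstrap interval -0.07 to 0.05). Because detection needed at least 10 reads, barcodes with fewer reads leave this mean and lower the number of detected barcodes instead. An effect of that kind is not excluded. Barcode base composition is excluded as the whole cause, since the difference was 1.93 over barcodes with 6 to 8 G or C bases. The number of detected barcodes differed by 1.98, and unequal numbers of plasmids in the delivered pool and unequal integration cannot be told apart here, because no count of the pool was used. An effect of the inserted sequence on the recovery of cells stays open as untested.

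Among barcodes with at least 1 read in only 1 library, median reads were 13 with 3 G or C bases and 23 with 8. The ratio was 1.77 (95% bootstrap interval 1.64 to 1.85). The step in listing at 10 reads, from 37.4% of strings with a highest count of 9 to 73.7% at 10, was followed by values between 73.7% and 77.5% for highest counts of 10 to 30 reads. Of the listed barcodes, 9523 (6.41%) stayed below 10 reads in all 5 gDNA libraries. Among pairs of listed barcodes 1 base apart, 736 belonged to the same inserted sequence, which is 2.03% of such pairs against 1.68% expected from the sizes of the sequences.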
